A study of Mus musculus with 12 samples.

How the data were processed

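RNA was measured in aortic valve leaflets of C57BL/6J;129SvEv mice at 2 months of age, in 4 genotype groups of 3 libraries each (CTRL, ECKO, SMKO and DKO). Per the labels' protocols, hearts were fixed in paraformaldehyde and frozen, sections of 20 μm were stained with hematoxylin, and entire leaflets were isolated by laser microdissection. Amplified cDNA was then tagmented with the Nextera XT kit, which does not keep the RNA strand, and read as paired ends of 75 bases on a MiSeq instrument. An isolated leaflet holds endothelial and interstitial cells, resident macrophages and melanocytes, so every value is an average over cell types. The labels call the libraries biological triplicates and assign no animal to a library.

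The authors deposited 1 table of 41709 genes. Per the file headers it holds whole-number total counts for each of the 12 libraries, and these deposited counts were the input for every test described here. The table also holds TPM, scaled by the authors within each library, per the file headers; no result here rests on TPM. A fold change and a p-value from the authors' comparisons of DKO with each of the other 3 groups stand beside them, per the file headers. The test behind those 3 comparisons, and whether the p-value was adjusted, are not given in the sources used here. Reads were mapped to GRCm39 per the submitters' processing notes; the aligner, the counting program, its use of strand and the gene annotation are not given in the sources used here. The annotation used here belongs to an older mouse build, so it served only for gene types, overlaps and neighbours, and no positions are printed. Of the identifiers in the table, 38619 were matched to it and 3090 were not. Protein-coding genes held 99.9% of all counts, so other kinds of transcript were close to unmeasured. Of the 65 genes selected by the naming rule below, 10 share an exon region with another protein-coding gene: Chpf2, Col4a1, Efemp2, Gata3, LTO1, Myoc, Naa80, Trf, Txndc11 and Ubl4a. Their counts are uncertain to that extent. For Gata3, Naa80, Trf and Ubl4a the other gene lies on the same strand, so strand would not separate the reads; for the other 6 it lies on the opposite strand, and the reads cannot be told apart without strand.

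Library totals ran from 74827 to 615665 counts, with a median of 321312, which is shallow for a transcriptome. Of the genes, 16588 had a count in any library. The edgeR filter filterByExpr (at least 10 counts, scaled to library size, in at least 3 libraries) kept 6296 genes, which held 93.1% of counts. A count of 0 in a group was read as up to 3 counts over the group's pooled total. Such floors and the 95% intervals, exact Poisson for levels and exact binomial for ratios, cover counting error only, since PCR copies without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise in every group: chi-square per degree of freedom between libraries of a group ran from 1.97 to 12.9, so no libraries were merged.

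Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust spread) in 1 model of all 12 libraries, with 8 residual degrees of freedom and Benjamini-Hochberg adjustment. The common biological coefficient of variation was 0.246. The 6 pairs of groups, an F test over the 4 groups, and the interaction DKO − ECKO − SMKO + CTRL were tested. A call is an adjusted p under 0.05, and standard errors are the absolute log2 fold change over the square root of F. Levels are TMM-scaled counts, as CPM, mean ± SD over 3 libraries. Every adjusted p of a gene is from this test unless another tool is named. For the targeted gene, an exact two-sided permutation test of log2 CPM was added; 3 libraries against 3 cannot give a p below 0.1.

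Before the data were examined, 33 gene lists for valve matrix, cell types and signalling were fixed, along with the designs, the alternatives to be tried and the naming rule. The 24 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it. No list call in any comparison held with an estimated correlation. Fry, which asks whether a list's genes move on balance in 1 direction, called the collagen and basement membrane lists in DKO against CTRL (adjusted p = 0.0279 for both) and no other list. Within a list, members were also adjusted over the list alone.

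The naming rule took, for each pair, the 10 largest rises and 10 largest falls among called genes whose 3 libraries of 1 group all lay above the 3 of the other. It added up to 10 called members of the fixed lists, or, where fewer than 10 genes passed, the 10 with the smallest p, said not to pass. List examples are the members with the smallest p. Efemp2 and sex-linked genes were always reported, and predicted gene models were left out.

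The pipeline was tested on simulated counts drawn from the real means, depths and spread of the 6296 genes, with 50 changed genes per size in each of 5 runs. For DKO against CTRL, it called 26.8% of genes changed by 1 on the log2 scale, 65.6% at 1.5, 83.2% at 2 and 95.6% at 3, with 4.20% false calls. For ECKO against CTRL the shares were 33.6%, 70.0%, 89.2% and 95.6%, and for SMKO against CTRL 17.6%, 61.2%, 80.0% and 91.2%. False calls were 6.42% and 5.53% for these 2. For DKO against ECKO recovery was 21.2%, 67.2%, 85.6% and 94.8%, and for DKO against SMKO 17.6%, 59.6%, 78.4% and 93.2%, with 4.73% and 4.74% false calls. A simulated list of 18 genes raised by 1 on the log2 scale was called in 5 of 5 runs and an unchanged list in 0 of 5, for each of these comparisons. Genes were simulated independently of each other, so these runs cannot show how often a list of correlated genes is called falsely. Differences between libraries that many genes share were not simulated either. The shares of false calls therefore do not cover such structure, which regroupings of the real libraries, given below, point to.

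Alternatives were DESeq2 1.42.0, limma-voom with library weights, other scalings and filters, fits of only the groups compared, a replicate block, a term for libraries 1 to 4 against 5 to 12, no robust spread, a log2 change of at least 1, and leaving out each library. Further settings were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.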

Results

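Aortic valve leaflets from mice aged 2 months were profiled by RNA sequencing in 4 genotype groups, each with 3 libraries. The labels give the codes CTRL, ECKO, SMKO and DKO without the gene. In the study as it is known, fibulin-4 (Efemp2), a matrix glycoprotein needed for elastic fibre assembly, was deleted in endothelial cells (ECKO), in smooth muscle cells (SMKO) or in both (DKO). Total counts were 576910, 561166 and 159857 for CTRL 1, 2 and 3, and 207637, 615665 and 379034 for ECKO 1, 2 and 3. They were 530233, 263589 and 74827 for SMKO 1, 2 and 3, and 247718, 455478 and 260449 for DKO 1, 2 and 3.

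Several libraries stood apart within their group. Mitochondrially encoded genes took 26.7% of counts in CTRL 3 and 28.5% in SMKO 3, the shallowest libraries, 24.1% in SMKO 2, and 10.5% to 20.98% in the other 9. Across the 12 libraries this share fell with log10 depth (Pearson r = -0.910, permutation p = 6e-05, Benjamini-Hochberg adjusted 0.00012; Spearman rho = -0.797, permutation p = 0.00296, adjusted 0.00559; 2 relations computed). It stayed at r = -0.857 without SMKO 3 and CTRL 3, and at r = -0.901 within groups. Gm10800, a satellite-like predicted gene, took 2.98% of counts in CTRL 3, 1.67% in SMKO 2, 0.980% in ECKO 1 and 0.974% in SMKO 3. Y-linked genes had 30 counts in CTRL 3, 89 in SMKO 1 and 28 in DKO 3, and at most 1 in any other library, so each group except ECKO included such a library. Xist, the other gene of the sex-linked list, had 0 counts in every library. The sex term used below thus rests on Y-linked counts alone. In SMKO 2, matrix genes lay near DKO: the fibrillar collagen list summed to 32634 CPM there, against 12030.0 in SMKO 1 and 11428 in SMKO 3. Much of that sum was Sparc, a collagen-binding protein, with 3072 counts in SMKO 2 against 742 for Col1a1.

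Efemp2 (ENSMUSG00000024909), the targeted gene, was present in CTRL, lower in ECKO, close to its detection limit in SMKO and without counts in DKO. Its level was 62.3 ± 24.8 CPM in CTRL, 18.5 ± 3.27 in ECKO, 2.27 ± 3.93 in SMKO and 0 in DKO (SD, n = 3). The counts were 58, 23 and 9 in CTRL, 3, 15 and 8 in ECKO, 4, 0 and 0 in SMKO, and 0 in each DKO library. Pooled over libraries, SMKO held 0.0763 of the CTRL level (95% interval 0.0203 to 0.202) and ECKO 0.322 (0.200 to 0.503). The mean level in CTRL was 20.0 times a floor of 3 counts over the DKO libraries, and that in ECKO 5.95 times this floor. DKO and SMKO could not be separated at this depth, and the counts in SMKO rested on SMKO 1. The exact permutation p was 0.1, the smallest that 3 against 3 allows, for every pair except DKO against SMKO (p = 1). In edgeR's test Efemp2 passed in DKO against CTRL (adjusted p = 0.000497) and against ECKO (0.0399), and missed in SMKO against CTRL (0.0612) and in ECKO against CTRL (0.939). It passed in SMKO against CTRL without CTRL 2. In DKO against ECKO its call was lost without any of the 3 ECKO, the 3 DKO, CTRL 1 or CTRL 3, with an adjusted p of up to 0.217 over all settings. The deleted exons are not known here, and Efemp2 overlaps Mus81 on the other strand.

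**Figure D1:**
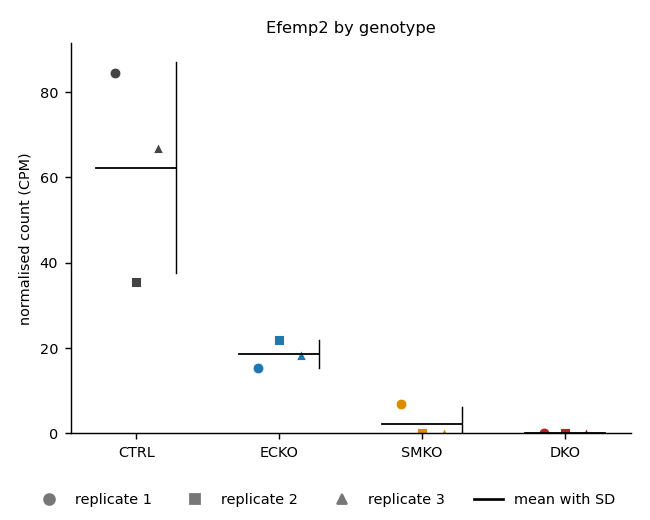
Normalised Efemp2 counts (CPM, vertical axis) per library in the 4 genotypes; points are libraries, horizontal lines means and vertical lines SD (n = 3), drawn no lower than 0. The CTRL libraries lie between 35.5 and 84.5 CPM, ECKO between 15.4 and 21.9, SMKO between 0 and 6.81, and DKO at 0.

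Whether any gene differed among the genotypes was asked with 1 test over the 4 groups. It called 19 of 6296 genes, led by Efemp2, Wnt9b, LTO1, Sphk1, Id4, Trpv4, Trf, Mall, Eln and Ccn2 (adjusted p from 0.000597 to 0.0293). Wnt9b, a secreted Wnt ligand, stood at 85.1 ± 8.12 CPM in CTRL, 123 ± 18.3 in ECKO, 209.6 ± 87.4 in SMKO and 300.1 ± 43.3 in DKO (SD, n = 3). Trf, which encodes the iron carrier transferrin, stood at 310.2 ± 43.1 in CTRL, 289 ± 25.0 in ECKO, 359 ± 152 in SMKO and 799.9 ± 259 in DKO. Ccn2, a matricellular target of TGF-beta and YAP, stood at 1080.1 ± 291 in CTRL and 3036 ± 560.0 in DKO. The count of 19 became 136 without SMKO 2, 51 without SMKO 1, 12 without CTRL 1, 8 without DKO 2, 5 without ECKO 2, 4 without DKO 1 or ECKO 3, and 3 without DKO 3.

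Valves lacking the gene in both cell types were compared with control valves to see what combined loss changed. Among the genes that rose, Eln, the core protein of elastic fibres, went from 163 ± 23.5 to 469 ± 90.2 CPM (log2 fold change 1.55 ± 0.29, SE), and Ltbp2, a microfibril-associated protein, from 286 ± 6.43 to 742.5 ± 172 (1.38 ± 0.31). Col4a1, a collagen IV chain of basement membranes, went from 170.1 ± 19.8 to 445 ± 50.5 (1.39 ± 0.29). Trpv4, a calcium channel opened by mechanical and osmotic stimuli, rose from 11.9 ± 3.72 to 80.9 ± 14.8 (2.81 ± 0.49). Sphk1, which makes sphingosine 1-phosphate, rose from 6.51 ± 1.86 to 52.8 ± 6.30 (3.01 ± 0.59). In CTRL 1, 2 and 3 these levels rest on few counts, 9, 5 and 2 for Trpv4 and 3, 5 and 1 for Sphk1. Ccl19, a chemokine for lymphocytes and dendritic cells, fell from 245 ± 81.2 to 24.4 ± 19.6 (-3.06 ± 0.55; all values mean ± SD, n = 3).

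In total 18 genes rose and 13 fell among the 6296 tested, with adjusted p from 0.000497 to 0.0495. The 3 DKO libraries lay outside the CTRL range for all 31, and for 17.8% of all tested genes, where chance gives 10%. Other rises were Cst6, a cysteine protease inhibitor (2.98 ± 0.63), Fgf1, a growth factor (1.91 ± 0.44), Wnt9b (1.82 ± 0.27), Mall (1.81 ± 0.37), LTO1 (1.74 ± 0.27), Atp13a3, a polyamine transporter (1.49 ± 0.32), and Mfge8, a secreted bridge to apoptotic cells (1.40 ± 0.30). Other falls were Edil3, a secreted integrin ligand (-2.65 ± 0.51), Myoc (-2.40 ± 0.48), Otud1, a deubiquitinase (-2.37 ± 0.54), Cd36, a fatty acid transporter (-2.30 ± 0.43), and the transcription factor Gata3 (-2.17 ± 0.48). Slc38a4, an amino acid transporter (-2.16 ± 0.52), Dsp, a desmosome protein (-1.91 ± 0.37), Ssbp2 (-1.69 ± 0.39) and Ogn, a small leucine-rich proteoglycan (-1.51 ± 0.34), fell as well.

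The 3 lists called were fibrillar collagens and collagen assembly, basement membrane, and the Notch pathway. Of 18 collagen list members none passed over all genes tested and 13 rose when adjusted over the list alone, among them Col6a1 (1.19 ± 0.31), Sparc, a collagen-binding protein (2.14 ± 0.54), and Col1a1 (1.29 ± 0.39). That list was higher in DKO by camera (adjusted p = 1.04e-10; adjusted p = 0.107 with an estimated correlation) and summed to 27433 ± 4272 CPM against 11176.5 ± 1931 in CTRL (SD, n = 3). Much of the DKO sum was Sparc, with 2584, 3769 and 3100 counts in DKO 1, 2 and 3, against 978, 1396 and 1070 for Col1a1. Sparc had 1508, 1257 and 425 counts in CTRL 1, 2 and 3, so the sums are not levels of collagens alone. Of 15 basement membrane members, Col4a1 passed over all genes and 6 rose adjusted over the list alone, including Lamb2 (0.85 ± 0.26) and Col18a1 (1.05 ± 0.35). The list had adjusted p = 5.22e-05 by camera, and adjusted p = 0.107 with an estimated correlation. Of 9 Notch pathway members, none passed over all genes and 3 fell adjusted over the list alone: the receptors Notch2 (-0.96 ± 0.28) and Notch1 (-0.88 ± 0.30) and the Notch target Hey1 (-1.38 ± 0.45). That call (camera adjusted p = 0.0115; adjusted p = 0.301 with an estimated correlation) was lost without CTRL 1, without DKO 3, where adjusted p reached 0.0839, and without a low-count filter. The fibulin and elastic fibre list was not called (adjusted p = 0.283), nor without Efemp2 itself (0.0778, a test added after the result had been seen), where 12 of its 18 other members were higher and 6 lower. Eln, Ltbp2 and the cross-linking enzyme Loxl2 (1.27 ± 0.31) rose and Efemp2 and Efemp1 (-1.22 ± 0.41) fell adjusted over the list alone. The median of all 19 was 0.40 and their mean -0.07; without Efemp2, whose fitted fold is no bound, these were 0.43 and 0.35.

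The count of 31 changed when single libraries were left out: it became 4 without CTRL 2, 6 without DKO 3, 8 without CTRL 1, 12 without DKO 1 and 15 without DKO 2. It became 67 without SMKO 1 and 127 without SMKO 2, libraries outside this pair, and both fits kept all 31 calls. With depth as a covariate it was 16. A fit with fewer libraries has less power, so a lost call alone does not show that the effect came from that library. Efemp2, LTO1 and Wnt9b passed in all 12 leave-one-out fits, Trpv4 in all but that without CTRL 2 (adjusted p = 0.0983), and every other named gene missed in at least 3 of them, with an adjusted p of up to 0.317 for Slc38a4 over all settings. LTO1 and Wnt9b passed in all 27 settings, while the Efemp2 call was lost by limma-voom with library weights (adjusted p = 0.0515).

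**Figure D2:**
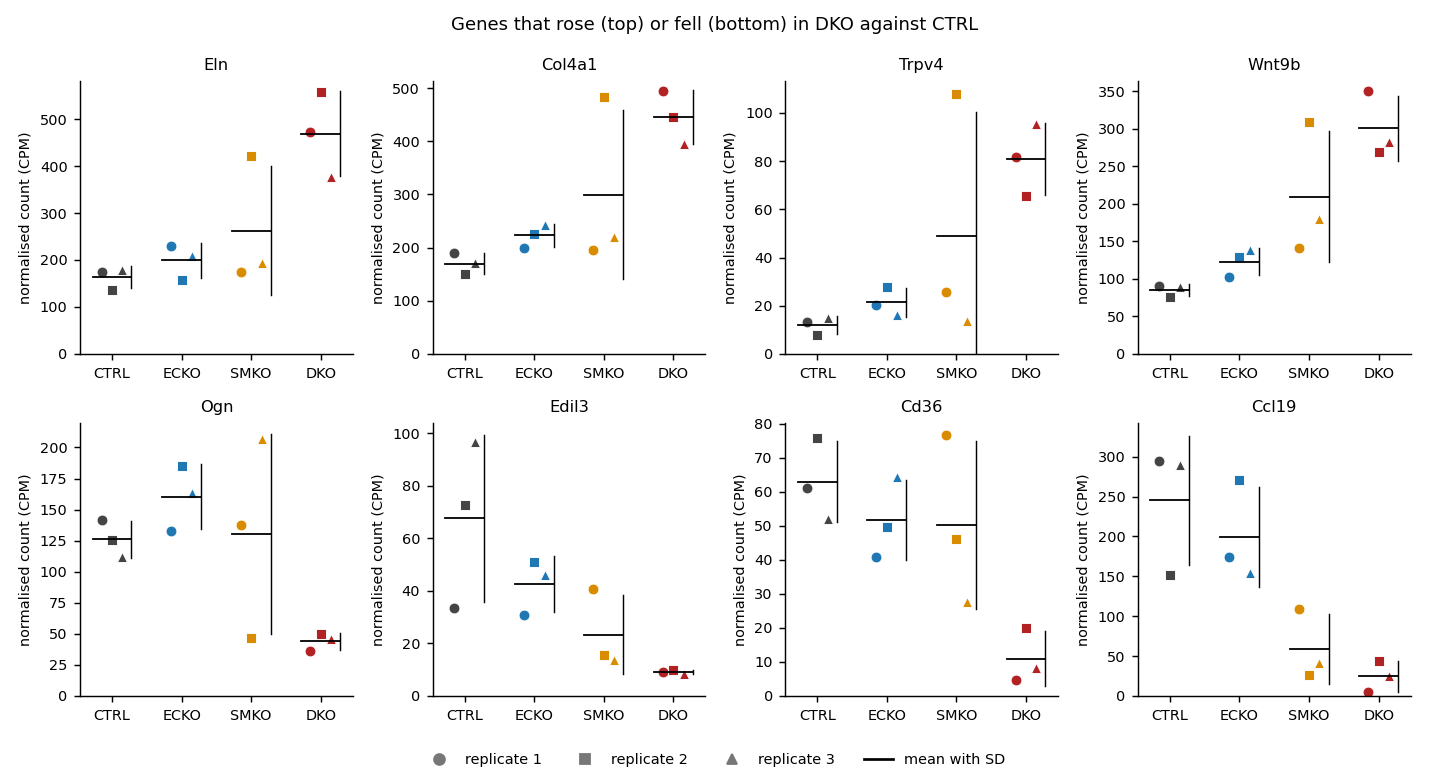
Normalised counts (CPM, vertical axes starting at 0) of 8 genes called in DKO against CTRL, per library in the 4 genotypes; points are libraries, horizontal lines means and vertical lines SD (n = 3), drawn no lower than 0. Eln, Col4a1, Trpv4 and Wnt9b lie higher in all 3 DKO than in all 3 CTRL libraries, and Ogn, Edil3, Cd36 and Ccl19 lower; SMKO 2 lies above the other SMKO libraries for Eln, Col4a1, Trpv4 and Wnt9b.

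The double knockout was set against ECKO, which asks what smooth muscle deletion added where the endothelial gene was already lost. For Id4, Dct and the melanocyte list ECKO itself lay below CTRL, though neither gene passed there. Their rise from ECKO to DKO thus need not be a departure from control. Fmnl2 lay higher in ECKO than in CTRL, without a call, so its fall from ECKO to DKO need not be one either. Sphk1 stood at 4.24 ± 3.71 CPM in ECKO and 52.8 ± 6.30 in DKO (log2 fold change 3.24 ± 0.61, SE), and Ccl2, a monocyte chemokine, at 9.70 ± 4.35 and 53.6 ± 18.5 (2.38 ± 0.56). In ECKO 1, 2 and 3 these rest on few counts, 0, 4 and 3 for Sphk1 and 1, 7 and 6 for Ccl2. Ccn2 rose from 1008 ± 189 to 3036 ± 560.0 (1.59 ± 0.36) and Eln from 199 ± 37.4 to 469 ± 90.2 (1.26 ± 0.29). Among endothelial genes, Prox1, a transcription factor of lymphatic and valve endothelium, fell from 49.0 ± 29.3 to 10.5 ± 5.46 (-2.48 ± 0.53), and Kdr, a VEGF receptor, from 55.7 ± 5.60 to 15.3 ± 4.02 (-1.76 ± 0.40; all SD, n = 3).

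Of the 6296 genes, 22 rose and 14 fell (adjusted p from 0.0126 to 0.0496), and the groups did not overlap for 35 of the 36, nor for 18.9% of all tested genes, where chance gives 10%. Among the rises were Serpinb1a, a protease inhibitor (2.73 ± 0.53), Dct, an enzyme of melanin synthesis (2.57 ± 0.49), Prxl2a (2.13 ± 0.44), Mall (1.90 ± 0.38), Trpv4 (1.81 ± 0.44), Id4, an inhibitor of helix-loop-helix factors (1.77 ± 0.30), Serpini1 (1.74 ± 0.40), Col18a1 (1.54 ± 0.36), Wnt9b (1.25 ± 0.26) and Ace, the angiotensin-converting enzyme (1.22 ± 0.29). Among the falls were Ccl19 (-2.83 ± 0.55), Ttc5 (-2.39 ± 0.58), Edil3 (-2.23 ± 0.53), Cd36 (-1.99 ± 0.44), Ogn (-1.86 ± 0.33), Lsamp (-1.73 ± 0.39), Fmnl2 (-1.50 ± 0.36) and Dock9 (-1.47 ± 0.32). The Ccl19 call was lost with the replicate number as a block.

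Camera called 6 lists here, and no call was lost when a library was left out. The melanocyte list was higher in DKO (adjusted p = 4.18e-08, and adjusted p = 0.171 with an estimated correlation). It summed to 149 ± 30.5 CPM in ECKO, 791 ± 381 in DKO and 541 ± 349 in CTRL (SD). Of its 6 members Dct passed over all genes and 5 rose adjusted over the list alone, such as Tyrp1 (3.95 ± 1.01). The endothelial list was lower (adjusted p = 1.79e-05, and adjusted p = 0.171 with an estimated correlation). It summed to 3024 ± 148 CPM in ECKO, 2462 ± 137 in DKO and 2423 ± 394 in CTRL (SD). In DKO the mean of its members lay -0.31 ± 0.18 from CTRL (log2, SE). Of its 17 members Prox1 and Kdr passed over all genes, and 4 fell adjusted over the list alone with Emcn (-1.34 ± 0.33) and Egfl7 (-1.83 ± 0.52). The basement membrane list was higher (adjusted p = 1.79e-05; adjusted p = 0.171 with an estimated correlation), with Col18a1 called over all genes and 4 of 15 members adjusted over the list alone, including Col4a2 (1.74 ± 0.53). The collagen list was higher too (adjusted p = 1.18e-05; adjusted p = 0.178 with an estimated correlation), with 0 of 18 members adjusted over the list alone by edgeR and 8 at an unadjusted p under 0.05. Matrix proteases and inhibitors and the unfolded protein response were higher (adjusted p = 0.00264 for both; adjusted p = 0.459 for both with an estimated correlation), each with 0 members adjusted over the list alone and 7 and 3 at an unadjusted p under 0.05; the protease call was lost without a low-count filter.

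The count of 36 fell when any library of either group was left out. It was 0 without ECKO 2, ECKO 3 or DKO 1, 1 without DKO 3, 3 without DKO 2 and 6 without ECKO 1. It was 14 without CTRL 1, 17 without CTRL 3, 66 without SMKO 1 and 144 without SMKO 2, and both SMKO fits kept all 36 calls. Fewer libraries also mean less power, so a lost call alone does not show that the effect came from that library. Over all settings the log2 fold change of Sphk1 ran from 2.99 to 3.48 and that of Cd36 from -2.96 to -1.76. With all libraries 680 genes had an unadjusted p under 0.05 (315 expected by chance), DESeq2 called 42 (25 higher) and limma-voom 95 (80 higher); with depth as a covariate edgeR called 10, and every named gene missed in at least 3 leave-one-out fits, with an adjusted p of up to 0.380 for Ccl2 over all settings.

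The calls in DKO against CTRL and in DKO against ECKO shared 17 genes, 11 higher and 6 lower, none in opposite directions. They were Sphk1, Trpv4, Wnt9b, Mall, LTO1, Eln, Atp13a3, Trf, Ildr2, Aebp1 and Capg on the higher side, and Efemp2, Ccl19, Edil3, Cd36, Ogn and Gas1 on the lower. Independent lists of these sizes would share 0.0629 higher and 0.0289 lower genes, and 20 simulations without any difference shared 0.1 on average and at most 1. Neither count can test the overlap, since the comparisons are not independent and simulations without a difference leave few genes to call. The covariance of the log2 fold changes was 0.238, against 0.101 in those simulations. Both comparisons use the 3 DKO libraries, which are too few to be split into independent parts.

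The double knockout was also set against SMKO, which asks what endothelial deletion added where the smooth muscle gene was lost. No gene passed edgeR's test: the smallest adjusted p was 0.235, 396 genes had an unadjusted p under 0.05 against 315 expected, DESeq2 called 3 and limma-voom 54. The genes nearest to a call included Ccn2, at 1011 ± 687 CPM in SMKO and 3036 ± 560.0 in DKO (log2 fold change 1.58 ± 0.37, SE), Trf (1.14 ± 0.30) and Sash1 (1.20 ± 0.31) on the higher side. Myoc at 184 ± 116 and 29.9 ± 7.60 (-2.56 ± 0.49), Cd36 at 50.1 ± 24.7 and 10.9 ± 8.02 (-2.18 ± 0.46), Ogn (-1.41 ± 0.36) and Fmnl2 (-1.65 ± 0.37) lay on the lower side, with none past the threshold (SD, n = 3). Frmd4a (2.72 ± 0.68), Ankrd33b (2.90 ± 0.74) and H2ac18, a histone gene, were the others. H2ac18 had 17, 11 and 5 counts in SMKO 1, 2 and 3 and 0 in each DKO library. Its mean level in SMKO was 16.5 times a floor of 3 counts over the DKO libraries, which is no bound on the fold. It varied within groups as well, with 14, 0 and 0 counts in CTRL 1, 2 and 3 and 0, 10 and 9 in ECKO 1, 2 and 3. The groups did not overlap for 9.55% of genes, where chance gives 10%.

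Camera called 6 lists in this pair. Higher in DKO were the collagens and the unfolded protein response (adjusted p = 0.00265 for both; adjusted p = 0.438 for both with an estimated correlation), YAP and mechanosensitive targets (0.0118; adjusted p = 0.438 with an estimated correlation), and hypoxia and glycolysis (0.0410; adjusted p = 0.438 with an estimated correlation). Lower were the endothelial list (0.00265; adjusted p = 0.438 with an estimated correlation) and the mitochondrially encoded genes (0.00740; adjusted p = 0.652 with an estimated correlation), the latter beside the high mitochondrial shares of SMKO 2 and SMKO 3. Adjusted over the list alone, Hyou1, an endoplasmic reticulum chaperone (1.91 ± 0.50), and Pdia6, a disulfide isomerase (0.89 ± 0.27), rose in the unfolded protein response list of 15, and Ccn2 in the YAP list of 16; 0 members of the other 4 did, with 0 to 4 at an unadjusted p under 0.05. Without SMKO 2, edgeR called 110 genes, 64 higher and 46 lower in DKO, and 7 lists. Without SMKO 1 only the endothelial and mitochondrial lists passed; hypoxia and glycolysis was also lost without SMKO 3, DKO 1 or DKO 3, the mitochondrial list without SMKO 2, SMKO 3 or DKO 2, and the YAP list without DKO 2. Without both shallowest libraries (CTRL 3 and SMKO 3) the endothelial, mitochondrial and hypoxia calls were lost. With depth as a covariate the mitochondrial and hypoxia calls were lost, the former also with the mitochondrial share; hypoxia and glycolysis, which held in 17 of 30 settings, was also lost with limma-voom weights, the strict filter, strict list members and fits of the 2 groups alone.

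Endothelial deletion alone was compared with control. No gene passed edgeR's test: the smallest adjusted p was 0.111, 273 genes had an unadjusted p under 0.05 against 315 expected, DESeq2 called 2 and limma-voom 0. Id4 was nearest, at 278 ± 35.6 CPM in CTRL and 92.7 ± 20.4 in ECKO (log2 fold change -1.54 ± 0.30, SE), followed by Dct, at 175 ± 117 and 35.0 ± 11.3 (-2.47 ± 0.48; SD, n = 3). Neither passed, nor did Nppc, which encodes C-type natriuretic peptide (1.44 ± 0.39), Fmnl2 (1.13 ± 0.32), the interferon-induced Slfn5 (1.07 ± 0.29) and Trim34a (1.95 ± 0.46), Txndc11 (1.42 ± 0.35), Chpf2 (1.48 ± 0.38), Safb (-1.42 ± 0.37) or Ubl4a (-1.49 ± 0.42). The groups did not overlap for 11.8% of genes, where chance gives 10%. Leaving out CTRL 3, DKO 3 or SMKO 2 gave 1 call each and leaving out DKO 1 gave 2.

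Melanocyte genes formed the clearest group in this pair. Of 6 members 4 fell adjusted over the list alone and 0 over all genes: Dct, Tyrp1 (-3.34 ± 1.03), Mlana (-3.43 ± 1.09) and Pmel (-3.02 ± 0.98), which make melanosomes and their pigment. The list was lower in ECKO (camera adjusted p = 2.13e-08; adjusted p = 0.238 with an estimated correlation) in every leave-one-out fit. Its summed level was 143, 121 and 181 CPM in ECKO 1, 2 and 3, against 411, 937 and 275 in CTRL 1, 2 and 3. Collagens (adjusted p = 0.00574; adjusted p = 0.578 with an estimated correlation) and endothelial genes (0.00910; adjusted p = 0.578 with an estimated correlation) were called higher, and MAPK feedback and targets lower (0.0152; adjusted p = 0.238 with an estimated correlation). None of their members passed adjusted over the list alone, and 1, 2 and 1 had an unadjusted p under 0.05: Plod2, a collagen-modifying enzyme (0.74 ± 0.26), Vwf (0.96 ± 0.44) with Flt1 (0.55 ± 0.27), and Spry1, an inhibitor of growth factor signalling (-0.86 ± 0.36). The collagen call was lost without CTRL 2, the endothelial call without CTRL 1, CTRL 2 or ECKO 3, and the MAPK call without CTRL 3 or ECKO 3, with adjusted p of up to 0.338, 0.140 and 0.0955. The endothelial call was also lost without a low-count filter, and the MAPK call with limma-voom weights and without both shallowest libraries (CTRL 3 and SMKO 3).

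Smooth muscle deletion alone was compared with control. No gene passed edgeR's test: the smallest adjusted p was 0.0612, for Efemp2 itself, 345 genes had an unadjusted p under 0.05 against 315 expected, and DESeq2 and limma-voom called 0. Wnt9b stood at 85.1 ± 8.12 CPM in CTRL and 209.6 ± 87.4 in SMKO (log2 fold change 1.29 ± 0.29, SE), Trpv4 at 11.9 ± 3.72 and 49.1 ± 51.2 (2.11 ± 0.55; 25.5, 108 and 13.8 CPM in SMKO 1, 2 and 3), and Fos, an immediate early transcription factor, at 57.1 ± 40.5 and 13.2 ± 12.5 (-2.87 ± 0.63; SD, n = 3). None of these passed, nor did Nr4a1 (-1.39 ± 0.37), H2-Q6 (1.97 ± 0.53), Fmnl2 (1.29 ± 0.34), Naa80 (1.31 ± 0.37) or Ift57 (-1.65 ± 0.46). The Trpv4 levels rest on 15, 21 and 1 counts in SMKO 1, 2 and 3. The groups did not overlap for 10.5% of genes, where chance gives 10%. Leaving out CTRL 2 gave 1 call.

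Camera called 5 lists in SMKO against CTRL. Mitochondrially encoded genes (adjusted p = 0.000164; adjusted p = 0.621 with an estimated correlation), collagens (0.000637; adjusted p = 0.402 with an estimated correlation) and basement membrane (0.0273; adjusted p = 0.402 with an estimated correlation) were called higher. YAP targets (0.00817; adjusted p = 0.402 with an estimated correlation) and immediate early and heat shock genes (0.0312; adjusted p = 0.402 with an estimated correlation) were called lower. Of 14 immediate early and heat shock members, Fos, Nr4a1, Junb (-1.27 ± 0.41) and Egr1 (-2.05 ± 0.64) fell adjusted over the list alone and 0 over all genes. In the other 4 lists no member passed either adjustment, and 1, 3, 1 and 3 members had an unadjusted p under 0.05, among them mt-Nd3 (0.85 ± 0.39), Sparc (1.53 ± 0.53), Col4a1 (0.82 ± 0.29) and, in the YAP list, Egr1. Without SMKO 2, whose collagen sum was given above, the collagen and basement membrane calls were lost (adjusted p = 0.258 and 0.462). No list passed without CTRL 2; the YAP call was also lost without SMKO 1, the basement membrane call without CTRL 1, and the immediate early call without CTRL 3, SMKO 1 or SMKO 2 and with a term for libraries 1 to 4. The mitochondrial call was lost with depth or the mitochondrial share as a covariate, and the basement membrane call with the mitochondrial share, with limma-voom weights and without a low-count filter.

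The single knockouts were compared with each other as well. No gene passed edgeR's test between SMKO and ECKO: the smallest adjusted p was 0.168, 239 genes had an unadjusted p under 0.05 against 315 expected, DESeq2 called 2 and limma-voom 0. Dct stood at 35.0 ± 11.3 CPM in ECKO and 262 ± 71.5 in SMKO (log2 fold change 3.01 ± 0.49, SE) and Tyrp1 at 7.23 ± 6.29 and 176 ± 194 (4.37 ± 1.01; SD, n = 3). Slc7a5 (1.41 ± 0.43) and Zfp944 (1.83 ± 0.56) lay higher in SMKO, and Nppc (-1.99 ± 0.48), Cdc42ep3 (-1.32 ± 0.34), Bcl2, an inhibitor of apoptosis (-1.33 ± 0.38), Grb10 (-1.08 ± 0.32), Clk1 (-1.07 ± 0.33) and Ankrd33b (-2.38 ± 0.75) lower, with none past the threshold. The groups did not overlap for 9.28% of genes, where chance gives 10%. Leaving out CTRL 2, CTRL 3 or DKO 1 gave 1 call each.

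Of 7 lists called in SMKO against ECKO, the melanocyte list was higher in SMKO (adjusted p = 5.79e-07; adjusted p = 0.342 with an estimated correlation), with 5 of 6 members adjusted over the list alone, such as Gpnmb (1.75 ± 0.55), and mitochondrially encoded genes were higher (7.09e-05; adjusted p = 0.680 with an estimated correlation). Both held in every leave-one-out fit. With the mitochondrial share as a covariate the melanocyte list alone passed, and with depth the mitochondrial and YAP calls were lost; the YAP call held in 15 of 30 settings and the immediate early call in 17. Basement membrane (adjusted p = 0.342 with an estimated correlation) and macrophage genes (adjusted p = 0.701 with an estimated correlation) were called higher, both with 0.0186 by camera. Contractile smooth muscle (0.0290; adjusted p = 0.342 with an estimated correlation), YAP targets (0.0444; adjusted p = 0.342 with an estimated correlation) and immediate early genes (0.0444; adjusted p = 0.396 with an estimated correlation) were called lower. No member of these 5 lists or of the mitochondrial list passed adjusted over the list alone. Col18a1 (0.94 ± 0.41), Ctss (0.89 ± 0.30), Tpm1 (-0.76 ± 0.35) and Fos (-2.16 ± 0.68) had the smallest p. The contractile sum was 722, 1100 and 700 CPM in ECKO 1, 2 and 3, against 592, 508 and 566 in SMKO 1, 2 and 3. ECKO 2, the highest, also held the most cardiomyocyte genes (1306 CPM). Without SMKO 2 the basement membrane, macrophage, contractile and immediate early calls were lost (adjusted p = 0.502, 0.473 and 0.399 for the first 3), and 3 lists remained, as also without SMKO 1; 4 remained when any 1 of the ECKO libraries was left out. The macrophage, contractile, YAP and immediate early calls were also lost with a sex term, and the macrophage, YAP and basement membrane calls without a low-count filter.

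The interaction asked whether the change in DKO differed from the sum of the changes in ECKO and SMKO. It called 2 genes, with an adjusted p of 0.0105 for both. Id4 stood at 278 ± 35.6 CPM in CTRL, 92.7 ± 20.4 in ECKO, 167 ± 34.3 in SMKO and 324 ± 160.5 in DKO (interaction 2.50 ± 0.43 on the log2 scale, SE). Fmnl2, a regulator of actin, stood at 34.9 ± 2.60 in CTRL, 72.0 ± 24.3 in ECKO, 78.1 ± 17.8 in SMKO and 28.2 ± 8.74 in DKO (-2.78 ± 0.49; SD, n = 3). Ogn (-1.75 ± 0.46), Tnxb, an extracellular matrix glycoprotein (-3.07 ± 0.74), and Sash1 (1.67 ± 0.42) did not pass. At an unadjusted p under 0.05 there were 392 genes against 315 expected, and DESeq2 called 1 gene and limma-voom 7.

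Camera called 5 lists for the interaction: endothelial genes lower (adjusted p = 2.47e-05; adjusted p = 0.248 with an estimated correlation), melanocyte genes higher (4.19e-05; adjusted p = 0.322 with an estimated correlation), the unfolded protein response higher (0.000819; adjusted p = 0.322 with an estimated correlation), YAP targets higher (0.00873; adjusted p = 0.248 with an estimated correlation) and mitochondrially encoded genes lower (0.0241; adjusted p = 0.770 with an estimated correlation). Adjusted over the list alone, Dct (2.04 ± 0.64) passed in the melanocyte list, Pdia6 (1.29 ± 0.37) in the unfolded protein response and Ccn2 (1.67 ± 0.51) in the YAP list; in the endothelial list 0 of 17 members passed and 6 had an unadjusted p under 0.05, led by Prox1 (-2.17 ± 0.72). The gene count of 2 became 57 without SMKO 2, 1 without CTRL 2, CTRL 3, ECKO 1 or ECKO 2, and 0 without ECKO 3, SMKO 1, DKO 1 or DKO 2. The YAP call was lost without CTRL 2 (adjusted p = 0.0507) and the mitochondrial call without CTRL 1, CTRL 2, ECKO 1, SMKO 2, SMKO 3 or DKO 2. The mitochondrial call held in 15 of 28 settings, and was also lost with depth or the mitochondrial share as a covariate, with limma-voom weights, without a low-count filter and with fry.

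**Figure D3:**
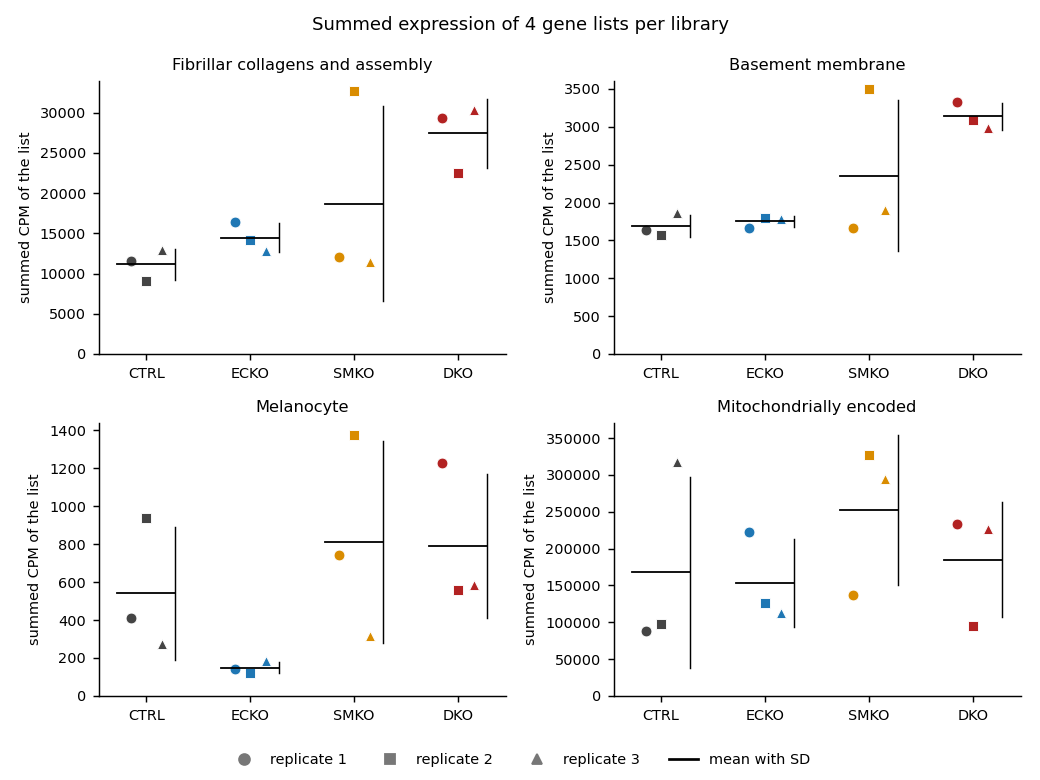
Summed CPM of 4 gene lists (vertical axes starting at 0) per library in the 4 genotypes; points are libraries, horizontal lines means and vertical lines SD (n = 3), drawn no lower than 0. Collagen and basement membrane sums are higher in all 3 DKO than in all 3 CTRL libraries, with SMKO 2 at 32634 and 3497 CPM, and melanocyte sums are lowest in ECKO. The collagen sums include Sparc, a collagen-binding protein with 3072 counts in SMKO 2.

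The authors' deposited table gave a p-value under 0.05 for 1151 genes in DKO against CTRL, 1070 in DKO against ECKO and 708 in DKO against SMKO, of 16588 genes with a value each, where chance gives 829. After Benjamini-Hochberg adjustment of those p-values, 63, 92 and 6 genes stayed under 0.05. In the authors' deposited table all 31 and all 36 genes called here in the first 2 pairs had the same sign and a p-value under 0.05. Across genes, which are not independent replicates, Spearman's rho between the authors' deposited fold changes and those fitted here was 0.992, 0.994 and 0.986.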

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

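The regroupings of libraries were planned, and the tests of the melanocyte genes were chosen after their result had been seen. The results in this part were singled out because a test of the difference itself, the interaction, found that the effect of smooth muscle deletion differed between valves with and without endothelial deletion. For genes these were Id4 (2.50 ± 0.43 on the log2 scale, SE) and Fmnl2 (-2.78 ± 0.49). For lists they were the medians of the endothelial list (-0.56), the YAP and mechanosensitive targets (0.59), the unfolded protein response (0.51), the melanocyte list (2.42) and the mitochondrially encoded genes (-0.40). With an estimated correlation none of these lists passed, with adjusted p from 0.248 to 0.770, although camera with the preset correlation called all 5. Of 100 regroupings of the 12 libraries, 7 gave at least the real count of 2 interaction genes, with 194 the highest other, and 26 gave at least the real 5 lists, with 10 the highest other, so chance cannot be excluded for either count. Counts far above the real one in some regroupings point to a structure among the libraries. Without SMKO 2 the interaction called 57 genes, and it called 1 without CTRL 2, CTRL 3, ECKO 1 or ECKO 2 and 0 without ECKO 3, SMKO 1, DKO 1 or DKO 2; with all libraries 392 genes had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 7.

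Melanocyte genes were low in all 3 ECKO libraries, which enters the interaction through ECKO. With log10 depth as a covariate, ECKO lay -2.19 ± 0.49 from the mean of the other groups (log2 summed CPM, SE; -2.08 ± 0.52 without it), which argues against depth. Fewer melanocytes in the captured tissue may be behind it but could not be decided: Dct, Tyrp1, Pmel and Mlana fell, while Mitf (-0.29 ± 0.49 against CTRL), which other cell types express as well, lay 4.13 standard errors from the mean of the 6 members. Variation between libraries unrelated to genotype stays open: the exact permutation p was 0.00455, the smallest that 220 assignments can give, and adjustment over 33 lists made it 0.15, so a single list could not have passed and this test decides nothing.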

How the results depend on the processing

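The settings with both shallowest libraries left out, a sex term, depth or mitochondrial covariates, mitochondrial genes with Gm10800 left out, camera on voom weights and Efemp2 left out of its list were added after the data had been seen, and the others were planned. No called list changed direction in any setting, and the called genes named in the report kept theirs. The collagen and basement membrane lists in DKO against CTRL passed in 29 of 30 settings, and missed with an estimated correlation. Where a count below differs from that with all libraries and edgeR, the cause was not tested, unless stated.

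DESeq2 called 37 genes over the 4 groups, 2 in ECKO against CTRL, 3 in DKO against SMKO, 2 in SMKO against ECKO and 1 for the interaction. Limma-voom with library weights called 86 over the 4 groups, 65 in DKO against CTRL, 95 in DKO against ECKO, 54 in DKO against SMKO and 7 for the interaction. Of the genes called by edgeR, DESeq2 shared 16 of 31 in DKO against CTRL and 20 of 36 in DKO against ECKO, and limma-voom 23 and 28. Rises and falls were 56 and 9 by limma-voom in DKO against CTRL and 80 and 15 in DKO against ECKO, against 18 and 13 and 22 and 14 by edgeR.

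With RLE size factors 5 lists passed in DKO against CTRL. With library size only, 1 gene passed in SMKO against CTRL, 19 in DKO against CTRL (12 higher), 14 in DKO against ECKO (11 higher) and 1 each in DKO against SMKO, SMKO against ECKO and the interaction, and 5 lists in DKO against CTRL; this scaling moved the median of all genes by -0.15 in DKO against CTRL, -0.13 in DKO against ECKO, -0.20 in SMKO against CTRL and -0.18 in SMKO against ECKO. Without a low-count filter, 218 genes passed over the 4 groups, 15 in ECKO against CTRL, 8 in SMKO against CTRL, 158 in DKO against CTRL, 173 in DKO against ECKO, 32 in DKO against SMKO, 16 in SMKO against ECKO and 28 for the interaction. The strict filter, which tests fewer genes, gave 19 in DKO against CTRL and 15 in DKO against ECKO.

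Fits of only the 2 groups compared gave 3 genes in ECKO against CTRL, 104 in DKO against CTRL, 189 in DKO against ECKO and 1 in SMKO against ECKO. With the replicate number as a block, 50 genes passed in DKO against CTRL, 29 of them among the 31, with Ccl19 (adjusted p = 0.110) and Myoc (0.123) lost. In DKO against ECKO 50 passed as well, 35 of them among the 36, with Ccl19 lost. The labels give no animal shared by a number. Libraries 1 to 4 are replicate 1 of each group, so their term is part of this block and the 2 settings are not separate checks. Libraries 5 to 8 are replicates 2 and 3 of CTRL and SMKO, and 9 to 12 those of DKO and ECKO. Library order among them cannot be told apart from endothelial deletion, and neither setting covers it. Gm10800 took 0.0825%, 1.67%, 2.98% and 0.974% of counts in libraries 5 to 8, and at most 0.184% in 9 to 12. Of 18 same-number pairs, 5 correlated above 0.1 (range -0.143 to 0.177), and 10 of 12 libraries correlated best with their own number. This is a hint from the data, and no pairing was used in the main fit. Without robust spread, 7 passed over the 4 groups, 2 in DKO against SMKO, 2 in SMKO against ECKO and 0 for the interaction. With an estimated correlation 0 lists passed in any comparison; fry called 0 lists in each comparison except 2 in DKO against CTRL. Strict list members gave 5 lists in DKO against CTRL.

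Without both shallowest libraries, 1 gene passed in ECKO against CTRL, 1 in SMKO against ECKO and 1 for the interaction, and 5 lists in DKO against CTRL. A sex term gave 29 genes over the 4 groups, 73 in DKO against ECKO and 4 lists in SMKO against ECKO. The depth covariate gave 9 genes over the 4 groups, 16 in DKO against CTRL and 10 in DKO against ECKO. The mitochondrial covariate gave 18 genes in DKO against CTRL, 20 in DKO against ECKO and 1 in DKO against SMKO, with 3 lists in SMKO against CTRL and 1 in SMKO against ECKO. Without mitochondrial genes and Gm10800, 5 lists passed in DKO against CTRL and 4 in SMKO against ECKO.

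Leaving out each library in turn gave 3 to 136 genes over the 4 groups, 4 to 127 in DKO against CTRL, 0 to 144 in DKO against ECKO, 0 to 110 in DKO against SMKO, 0 to 2 in ECKO against CTRL, 0 to 1 in SMKO against CTRL and in SMKO against ECKO, 0 to 57 for the interaction and 7 to 91 for smooth muscle deletion averaged over endothelial status. Every highest count came without SMKO 2 where it exceeded 2, except the 91, without SMKO 1. Lists numbered 2 to 8 in DKO against CTRL, 6 to 9 in DKO against ECKO, 2 to 9 in DKO against SMKO, 2 to 5 in ECKO against CTRL, 0 to 8 in SMKO against CTRL, 3 to 8 in SMKO against ECKO and 3 to 7 for the interaction. The log2 difference of Efemp2 ran from -6.25 to -5.64 in DKO against CTRL, -4.40 to -4.15 in DKO against ECKO, -1.48 to 0 in DKO against SMKO, -1.98 to -1.36 in ECKO against CTRL, -5.90 to -4.42 in SMKO against CTRL and -4.27 to -2.79 in SMKO against ECKO. Since DKO had 0 counts, the differences with DKO depend on the constant added before the log and do not measure a fold. The same holds for SMKO without SMKO 1. The fitted log2 values, which are no bounds, ran from -4.33 to 0.00 for Efemp2 DKO vs SMKO and from -2.69 to 1.65 for Efemp2 interaction; without SMKO 1, which held all counts of its group, the first had no direction and the second changed direction, by construction. Over these fits the named genes, counted once per comparison and fit, stayed on their side of the threshold 904 times, lost a call 283 times and gained a call 23 times, and the called lists kept their call 375 times and lost it 57 times. Depth limits the genes tested to 6296 of the 16588 with counts.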

Other observations

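The regroupings reported here were planned, except that the contrast averaging over endothelial status was added after the data had been seen, and the tests of SMKO 2 and of the collagen and basement membrane lists were chosen after their results. For the 19 genes differing among the 4 groups, 9 of 100 regroupings of the 12 libraries gave as many, with 128 the highest other, so chance cannot be excluded. For smooth muscle deletion averaged over endothelial status, 13 genes passed, among them Wnt9b (1.27 ± 0.19, log2, SE), LTO1 (1.13 ± 0.19) and Trpv4 (1.96 ± 0.35), and 2 of 100 regroupings, the real one included, gave as many, with 148 the highest other; since the contrast was chosen after the data had been seen, this share does not exclude chance. That count became 91 without SMKO 1, 29 without SMKO 3, and 7 without CTRL 3, ECKO 2 or ECKO 3, 8 without ECKO 1 or DKO 3. Without SMKO 2 it was 9, of which 5 were among the 13. DESeq2 called 44 and limma-voom 12, each sharing 8 of the 13. With edgeR the count was 5 with the mitochondrial share and 6 with depth as a covariate, 23 with the term for libraries 1 to 4, 26 with a sex term and 149 without a low-count filter. Regroupings with several times the real count point to a structure among the libraries.

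Between 2 groups of 3 libraries there are 10 splits, too few for a share under 0.05. The numbers of splits giving as many genes as the real one were 1 for DKO against CTRL (31, highest other 0), 1 for DKO against ECKO (36, highest other 1), and 10 for DKO against SMKO (0, highest other 77), ECKO against CTRL (0, highest other 1), SMKO against CTRL (0, highest other 4) and SMKO against ECKO (0, highest other 1). The counts of 0 are from edgeR, beside 396, 273, 345 and 239 genes at an unadjusted p under 0.05, 3, 2, 0 and 2 by DESeq2 and 54, 0, 0 and 0 by limma-voom. The split that exchanged SMKO 2 with DKO 3 gave the 77, which points to a structure of the samples. For lists the numbers were 8 for DKO against CTRL (3 lists, highest other 5), 3 for DKO against ECKO (6, highest other 7), 4 for DKO against SMKO (6, highest other 11), 2 for ECKO against CTRL (4, highest other 6), 4 for SMKO against CTRL (5, highest other 6) and 1 for SMKO against ECKO (7, highest other 5).

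SMKO 2 lay near the DKO libraries. On a scale over 50 genes where the mean of CTRL and ECKO is 0 and that of DKO is 1, chosen with the library in question left out, it stood at 1.19, against 0.844 to 1.02 for left-out DKO libraries, -0.0481 for SMKO 1 and -0.214 for SMKO 3. Low-quality RNA as the whole cause is argued against, since the other libraries with at least 0.9% of counts on Gm10800 reached 0.192 at most. A swap with a DKO library is argued against because no DKO library was out of place, while a single wrong label may be the cause and a truly more affected SMKO valve would give the same value. List sums do not settle the label, since some lay outside the DKO range and others close to it. Cartilage and bone genes summed to 72940 CPM in SMKO 2 against 27739 to 32874 in DKO. Mgp made up most of that sum, with 13263 counts in SMKO 2, where Spp1 had 212 and Comp 203. It thus reads Mgp more than the list. Proteoglycans summed to 51737 in SMKO 2 against 32776 to 43035 in DKO. Basement membrane genes summed to 3497 against 2990 to 3332. Efemp2 does not settle it: 1.33 counts would be awaited in SMKO 2 at the level of SMKO 1, and 0 were seen.

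Collagen and basement membrane lists were higher in DKO than in CTRL by 0.78 ± 0.17 and 0.62 ± 0.15 (difference of list means, log2, SE). Depth is argued against as the cause, with 0.777 ± 0.18 and 0.629 ± 0.16 once log10 depth was a covariate, and so is the mitochondrial share as a sign of RNA quality, with 0.767 ± 0.17 and 0.622 ± 0.16. A higher share of interstitial cells stays open: less the mean of the proteoglycan list the differences were 0.962 ± 0.22 and 0.807 ± 0.24, but members of that list went both ways, with an SD of 0.99 between their log2 fold changes. An effect of combined deletion on expression within cells cannot be told apart from such a shift in cell types.

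Values outside the comparisons were these. Cardiomyocyte genes summed to 1306 CPM in ECKO 2. Erythrocyte and platelet genes summed to 5571 CPM in ECKO 2, 3432 in CTRL 3, 3361 in ECKO 3 and 2276 in SMKO 1. The other libraries held 41.0 to 618, and the DKO libraries among them 123 to 460. Among the 20 tested genes nearest to Efemp2, Cst6 was the only gene called in DKO against CTRL, and 9.35% of 5841 such windows held at least 1 called gene. Efemp2 left aside, the genes called in DKO against ECKO were read in SMKO against CTRL, which shares no library with it. There 29 of 35 had the same sign, and the mean shift was 0.396 on the log2 scale (permutation p = 0.1, the smallest possible). Of those called in DKO against CTRL, 22 of 30 had the same sign in SMKO against ECKO, and the mean shift was 0.390 (permutation p = 0.2). Both rested on SMKO 2: without it, in a test added after the result had been seen, 16 of 35 and 18 of 30 had the same sign. Lists tested but called in no comparison had as their smallest adjusted p 0.0533 for interferon response, 0.0872 for complement, 0.139 for MHC class II, 0.173 for TGF-beta and BMP, 0.187 for mesenchymal genes, 0.253 for cartilage and bone, 0.319 for Wnt, 0.405 for chemokines and 0.542 for proteoglycans.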
